A study of Mus musculus with 2 samples.

How the data were processed

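Small RNA was sequenced from 2 mouse MSC lines, 1 library per genotype, f/f and null for Dicer. Per the labels' protocols, total RNA was extracted with Qiazol from cells grown close to confluence in alpha-MEM with 10% fetal bovine serum, RNA of 15 to 50 nt was taken from a 15% denaturing gel, and libraries followed the Illumina small RNA protocol. The authors deposited raw counts: each file lists distinct read sequences with the number of times each was observed, with no gene names and no coordinates. Reads ran from 5 to 36 nt, and each sequence occurred once per file. A peak at 36 nt, the longest length, holds inserts that were at least as long as the read, so longer RNAs are truncated there. Per the submitters' processing notes the genome build was mm9; the trimming tool and the aligner are not given in the sources used here. The second library's title ends in the number 2, whose meaning is not stated in the labels.

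Groups were taken from the genotype label. The libraries held 9943989 reads (f/f) and 6291599 reads (null). Reads of at least 18 nt were matched to GENCODE M21 transcripts (GRCm38), in sense and without mismatch, and shorter reads were kept as a class of their own. A read that matched several classes was assigned in the order miRNA, rRNA, tRNA, snoRNA, snRNA, other small RNA, mitochondrial RNA, and mRNA or lncRNA exons. All coordinates are GRCm38 positions of the annotation. That annotation gives miRNA hairpins without mature arms (2199 hairpins, of which 1178 have a Mir symbol), so a read counted as miRNA when it lay within a hairpin, and its arm was set by the side of the hairpin midpoint it fell on. Reads shared by identical hairpins were joined into 1 species, named by all hairpins it could come from. The annotation has 2 nuclear tRNA genes; a full nuclear tRNA set, the 45S rRNA and the genome sequence were not used here, so reads from these count as unmatched. For 3 genes annotated as miRNA whose symbols name a snoRNA or tRNA, the class followed the symbol.

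CPM, read counts scaled to an equal library total, were computed over all reads in a file. Shares carry exact Clopper-Pearson intervals, counts exact Poisson intervals and ratios the exact conditional interval of 2 counts, all at 95%. A ratio against 0 reads used a floor of 3 counts and is given as a bound. Lists were compared with 10000 random lists of the same size matched on f/f abundance. These were drawn from all species with at least 100 f/f reads, the list's own members included. No test across genotypes was made, because each had 1 library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. On simulated data for the comparison of f/f with null, 400 of 400 hairpin reads were matched and 0 of 400 shuffled reads. A further check simulated 400 species, of which 200 were changed. There the ratio's interval held the true value for 95% at fold 1, 97.0% at fold 4, 94.0% at fold 30 and 98.5% at fold 200. The reads were cut without error from the same hairpins and the counts were Poisson draws. These checks therefore do not cover mismatches, untemplated bases, PCR copies or variation between libraries.

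The groups, the main measures, 20 lists of miRNAs, the rule for naming miRNAs and the alternative settings not named as later ones were chosen before the data were examined. The lists were let-7, miR-17-92, mesenchymal, miR-23/27/24, miR-30, miR-15/16, miR-34, Hox, Dlk1-Dio3, Sfmbt2, mirtrons and other Drosha-independent miRNAs, the Dicer-independent miR-451a, hairpins that overlap structured RNA, and markers of haematopoietic, endothelial, muscle, epithelial, neural, pluripotent and liver cells. Named were all let-7 species with at least 100 f/f reads, the 15 most abundant species of f/f and 10 of null, the 5 lowest and 5 highest ratios among species with at least 1000 f/f reads, species with at least 100 null reads at 0.5 or more of their f/f level (of which a selection is printed), and the leading 2 of each list with at least 100 reads in either library. In other classes these were the 3 genes with most reads per class and library and the 5 most abundant sequences per library. Comparisons among reads up to 23 nt, single miRNAs and RNA classes per snoRNA and snRNA read, Rnu5g on reads of no other gene, matches without the last 3 nt, the mRNA and lncRNA class without Tmem38b and Dnm3os, species within 2-fold at 18 to 23 nt, blood and epithelial markers under 100 reads, miR-3535-5p's overlap and other features outside this rule were chosen after their values were seen. Alternatives changed the denominator, the scale, the length window, the minimum copy number, the matching rule, the hairpins counted and the minimum number of f/f reads.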

Results

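Small RNAs were sequenced from immortalized clonal mouse mesenchymal stem cell (MSC) lines, fibroblast-like cells of adult bone marrow on the C57BL/6 background. The 2 libraries came from cells with f/f alleles of Dicer, which the labels treat as wild type, and from Dicer knockout cells, called null here. Dicer is the RNase III enzyme that cuts precursor hairpins into mature miRNAs of about 22 nt. The f/f library held 9943989 reads of 410792 distinct sequences and the null library 6291599 reads of 909932 distinct sequences. A count of 0 allowed up to 0.302 CPM in f/f and 0.477 CPM in null. With 1 library per genotype, no difference had a replicate check, no test across libraries was possible and no p-value is given. All intervals are 95% intervals of counting error only, since reads amplified by PCR are not independent molecules.

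Dicer1, the targeted gene, was seen only as short fragments of its mRNA. It lies on chromosome 12 (104687742 to 104751952, minus strand, GRCm38), and 16 f/f reads and 44 null reads matched its exons, 4.35-fold more in CPM in null (2.40 to 8.25). Which exon was deleted is not stated in the labels, so these fragments did not check the genotype. Nr6a1, an orphan nuclear receptor gene named in the series title as a let-7 target (chromosome 2, 38723370 to 38927688, minus strand), gave 30 f/f reads and 87 null reads, a ratio of 4.58 (2.996 to 7.192). Fragments of all mRNA and lncRNA exons together were 4.81-fold more frequent in null (4.78 to 4.84). Without Tmem38b and Dnm3os, whose reads are uncertain and made up 39.2% of the class in f/f, they were 7.501-fold more frequent (7.44 to 7.57), above the interval of Nr6a1 and inside that of Dicer1. Relative to snoRNA and snRNA reads, the log2 ratio of the class was 0.15 with those 2 genes and 0.79 without them.

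The first comparison asked how far the miRNA population of these cells depended on Dicer. Reads of 21 to 23 nt, the size of Dicer products, made up 71.1% of the f/f library and 18.3% of the null library. At 22 nt alone the shares were 45.6% and 10.4%. Longer reads were more frequent in null: reads of 24 to 35 nt were 12.1% of f/f and 40.3% of null, and reads of 36 nt, the longest the files hold, 1.68% and 14.4%. Reads of 30 to 32 nt were 1.55% of f/f and 14.2% of null. Reads that matched an annotated miRNA hairpin were 59.6% of f/f (59.56 to 59.62) and 2.17% of null (2.16 to 2.18), a 27.5-fold lower share (27.3 to 27.6). miRNA reads no longer than 23 nt were 57.9% of all f/f reads and 0.567% of all null reads, a 102-fold lower share (101 to 103). Among all reads no longer than 23 nt, they took 67.2% and 1.25%, 53.7-fold lower (53.2 to 54.3).

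**Figure D1:**
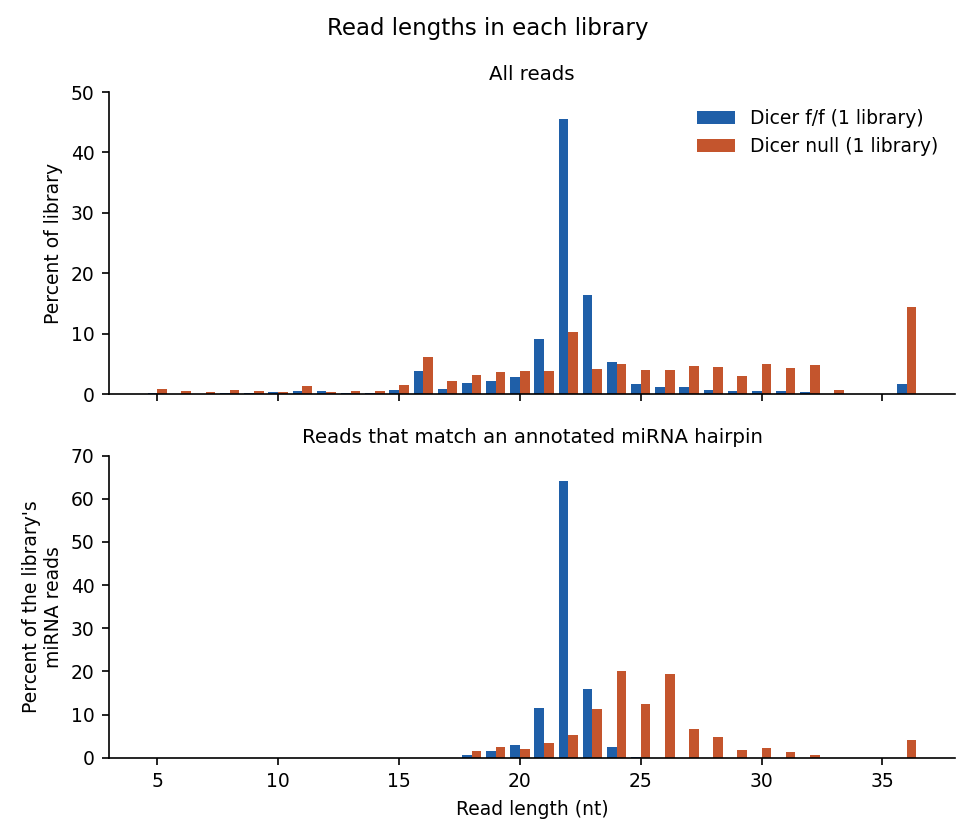
Percent of all reads of each library (top) and percent of its miRNA reads (bottom) against read length in nt, for f/f and null. At 22 nt the f/f library held 45.6% of all its reads and 64.2% of its miRNA reads, against 10.4% and 5.35% in null.

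The let-7 family, named in the series title, supplied 183650 CPM in f/f and 2261 CPM in null, 81.2-fold lower (79.9 to 82.6). All 17 let-7 and miR-98 species with at least 100 f/f reads were more than 2-fold lower in null. Most abundant was let-7c-5p (TGAGGTAGTAGGTTGTATGGTT), with 759421 f/f reads and 3762 null reads, 128-fold lower (124 to 132). Its hairpins are Mirlet7c-1 in an intron of the noncoding host gene Mir99ahg (chromosome 16, 77599657 to 77599750, plus strand) and Mirlet7c-2 in an exon of the noncoding gene Lncppara (chromosome 15, 85706603 to 85706697, plus strand). Mirlet7b lies in the same Lncppara transcript unit (chromosome 15, 85707319 to 85707403), and let-7b-5p (TGAGGTAGTAGGTTGTGTGGTT) was 98.9-fold lower (95.4 to 103). The hairpins Mirlet7a-1, Mirlet7f-1 and Mirlet7d lie together in exons of the lincRNA 6720427I07Rik on chromosome 13 (48536012 to 48538272, minus strand). From these and further copies, let-7a-5p was 53.2-fold lower, let-7f-5p 78.6-fold lower and let-7d-5p 138-fold lower (122 to 157). Mirlet7i overlaps the pseudogene D630033A02Rik on chromosome 10 (122985640 to 122985724), and let-7i-5p was 36.5-fold lower. Mirlet7g lies in an intron of Wdr82 on chromosome 9 (106178840 to 106178927), and let-7g-5p was 70.1-fold lower. Mir98 and Mirlet7f-2 lie in introns of Huwe1 on chromosome X, and miR-98-5p was 33.5-fold lower.

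Over all read lengths, differences were smallest for Mirlet7e, in an intron of Spaca6 on chromosome 17 (17830352 to 17830444). From this hairpin let-7e-5p was 15.3-fold lower (14.5 to 16.2) and let-7e-3p 3.09-fold lower (2.36 to 4.11), from 313 to 64 reads. Of the other 3p arms, let-7i-3p was 111-fold lower, let-7b-3p 18.1-fold lower, let-7d-3p 49.5-fold lower, miR-98-3p 33.7-fold lower and let-7g-3p 71.5-fold lower (12.6 to 2849), the last with 1 null read. Reads shared by let-7a and let-7c were 58.5-fold lower on the 5p arm and 148-fold lower on the 3p arm. The family's median log2 ratio of -5.87 lay at percentile 43.5 of 10000 random lists matched on f/f abundance. Those lists were drawn from all species, let-7 included, so the percentile is not a comparison with other miRNAs alone. With reads that match a transcript as the scale, let-7e-3p was at a log2 ratio of 0.12 and 16 of the 17 species were still more than 2-fold lower; with snoRNA and snRNA reads as the scale, all 17 were.

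Across the 295 miRNA species with at least 100 f/f reads, the median log2 ratio of null to f/f was -5.18 (interquartile range -6.93 to -3.35), a 36.2-fold lower level. More than 2-fold lower were 265 species, 223 were more than 10-fold lower and 85 more than 100-fold lower, while 18 lay within 2-fold and 12 were more than 2-fold higher. No null read was found for 36 species. The 3p arms were lower than the 5p arms, with medians of -6.38 over 133 species and -4.51 over 162 species. Scaling to reads that match a transcript shifted every log2 ratio by 1.75 and gave 237 species lower, 30 within 2-fold and 28 higher. Scaling to snoRNA and snRNA reads shifted every ratio by -2.12 and gave 284 lower, 7 within 2-fold and 4 higher.

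**Figure D2:**
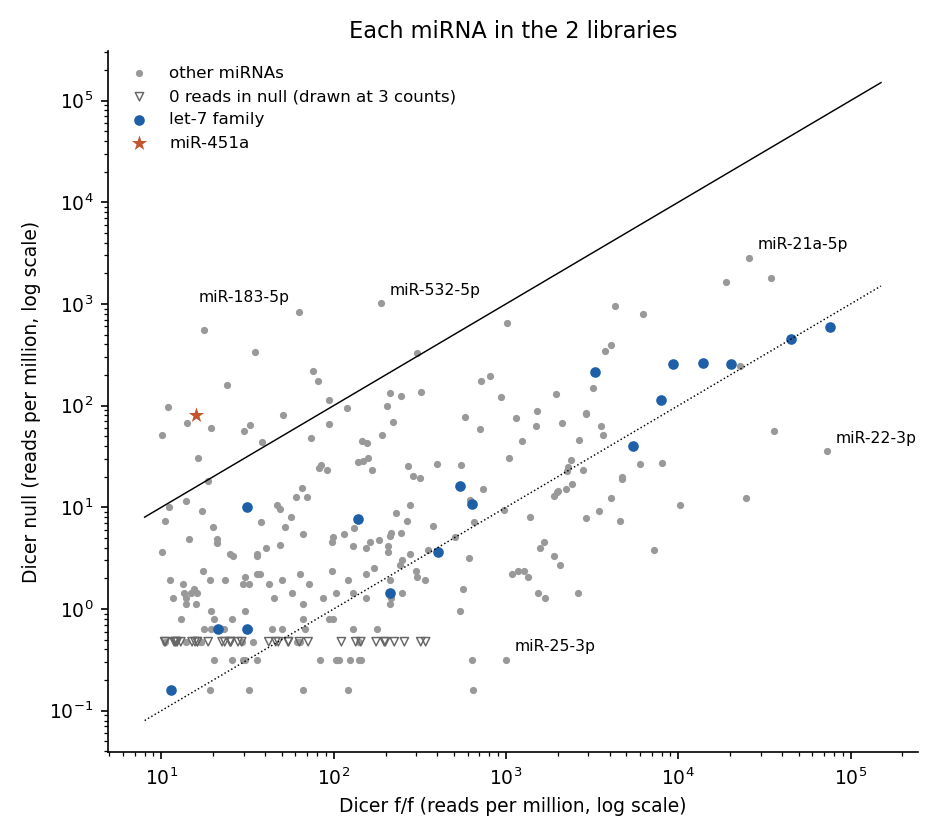
CPM in null against CPM in f/f, both on log axes, for the 295 miRNA species with at least 100 f/f reads; let-7 species are blue, miR-451a is a star and triangles are species with 0 null reads drawn at the 3-count floor. The solid line marks equal levels and the dotted line a 100-fold lower level in null; 265 species were more than 2-fold lower and 12 more than 2-fold higher.

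The mesenchymal group, miRNAs usually abundant in fibroblasts, was 38.4-fold lower as a sum (37.97 to 38.75), with 26 of 28 species more than 2-fold lower. Within it, miR-22-3p (AAGCTGCCAGTTGAAGAACTGT), the most abundant sequence of the f/f library, had 72847 CPM in f/f and 35.9 CPM in null, 2028-fold lower (1780 to 2321). Its hairpin Mir22 lies in exons of Mir22hg on chromosome 11 (75463716 to 75463810, plus strand). Also in this group, miR-145a-5p was 637-fold lower (574 to 709) and miR-125b-5p 92.7-fold lower, whereas miR-21a-5p, from an exon of Vmp1, was 9.04-fold lower (8.90 to 9.18), or 77.0-fold lower with reads of 18 to 23 nt alone. The hairpins Mir199a-1, Mir199a-2 and Mir199b gave a shared 3p species 2022-fold lower (1618 to 2563), with 77 null reads, while miR-199a-5p was 11.6-fold lower (11.3 to 11.8). Reads of the 3p arm that matched miR-199a hairpins alone, mostly of 24 nt or longer, were counted apart. They had 84 f/f and 142 null reads, 2.67-fold higher in null (2.03 to 3.54), and the 2022-fold value leaves them out.

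The miR-23/27/24 clusters were 138-fold lower (131 to 146), with 10 of 11 species more than 2-fold lower, among them miR-23a-3p (960-fold) and miR-24-3p (298-fold). The miR-30 family was 31.2-fold lower with all 10 species lower, including miR-30c-5p (55.6-fold) and miR-30d-5p (82.1-fold). The miR-34 family, a group induced by p53, was 68.5-fold lower with all 6 species lower, including miR-34c-5p (140-fold) and miR-34a-5p (21.05-fold). As a sum, the miR-17-92 cluster and its paralogs, which promote proliferation, were 15.4-fold lower, with 15 of 16 species lower. In that group miR-93-5p was 72.2-fold lower and miR-106b-5p, from the same Mcm7 locus on chromosome 5, 4.47-fold lower (4.35 to 4.59); miR-106b-5p alone gave 6021 of the 8200 null reads. The miR-15/16 family was 14.1-fold lower with 8 of 10 species lower. In it miR-16-5p was 19.2-fold lower, miR-15b-5p 7.96-fold lower and miR-322-5p 1.53-fold lower (1.48 to 1.59). With reads up to 23 nt alone, miR-15b-5p was 50.8-fold and miR-322-5p 10.0-fold lower. Of their null reads, 84.3% and 84.7% were longer than that. The miRNAs encoded in Hox clusters were 13.2-fold lower with all 3 species lower, and of these miR-196b-5p was 10.9-fold and miR-196a-5p 21.5-fold lower. The rodent cluster in an intron of Sfmbt2 was 4.20-fold lower as a sum, with 25 of 26 species lower; miR-669a/669p-5p was 4.19-fold and miR-467c-5p 3.24-fold lower, while miR-466c-5p was 2.16-fold higher (1.97 to 2.37).

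The medians over species, in which each miRNA counts equally, ordered the families differently from the sums. The median log2 ratio was -6.97 for miR-23/27/24, -6.86 for miR-34 and -6.84 for the Drosha-independent miRNAs, at percentiles 8.17, 9.24 and 7.01 of random lists matched on f/f abundance. It was -5.63 for miR-17-92 and -5.50 for the mesenchymal group, at percentiles 70.9 and 86.2. For the miR-30, miR-15/16 and Hox groups it was -4.47, -4.62 and -4.42, at percentiles 90.5, 95.1 and 85.7, and for the Sfmbt2 cluster -4.82, at percentile 49.1.

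The lowest null to f/f ratios were ranked among species with at least 1000 f/f reads and at least 1 null read. Beside miR-22-3p and the shared miR-199 3p species, these belonged to miR-129-5p, miR-25-3p and miR-365-3p. They were 4055-fold (728 to 160189), 3149-fold (871 to 26006) and 1995-fold (552 to 16474) lower, with 1, 2 and 2 null reads. Another 10 species with at least 1000 f/f reads had no null read, so their ratios are bounds only and are not ranked here. Mirtrons and other miRNAs made without Drosha but with Dicer were 445-fold lower as a group (308 to 670), with all 5 species lower. In that group miR-320-3p had 12728 f/f and 15 null reads (537-fold lower) and miR-484-5p 5381 and 6 reads (567-fold lower).

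The miRNA made without Dicer differed the other way. miR-451a, whose hairpin is cut by Ago2, had 157 f/f and 508 null reads, 15.8 and 80.7 CPM, 5.11-fold higher in null (4.27 to 6.16). Its 23-nt form AAACCGTTACCATTACTGAGTTT had 110 f/f and 375 null reads, and its hairpin Mir451a lies on chromosome 11 (78073170 to 78073241, plus strand). Scaled to snoRNA and snRNA reads, the log2 ratio of miR-451a was 0.23 in place of 2.35, and its interval then included no change.

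miRNA reads that remained in null differed in length and arm from those of f/f. Reads of 24 nt and longer were 2.82% of miRNA reads in f/f and 73.8% in null. As a share of the library these longer reads were nearly as frequent in null, at 0.951 of the f/f level (0.944 to 0.959). The 5p arm held 70.03% of miRNA reads in f/f and 88.9% in null. Reads up to 23 nt were 85.4-fold lower on the 5p arm and 185-fold lower on the 3p arm, while longer reads were at 0.991 of the f/f level on the 5p arm and 0.678 on the 3p arm. Of the miRNAs abundant in null, miR-21a-5p had 88.7% of its null reads at 24 nt or longer, miR-16-5p 80.6%, miR-106b-5p 82.2% and miR-199a-5p 56.2%. By contrast miR-22-3p had 4.0% there. With reads of 18 to 23 nt alone, miR-16-5p was 98.5-fold, miR-106b-5p 24.7-fold and miR-199a-5p 26.3-fold lower.

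Most 5p reads kept their start in null, and few kept their end. Over 87 miRNAs of the 5p arm with at least 1000 f/f reads, 98.4% of f/f reads and 96.5% of null reads (96.3 to 96.6) began at the commonest f/f 5′ end. The commonest 3′ end was used by 78.7% of f/f and 10.6% of null reads. Over 69 miRNAs of the 3p arm, 92.2% of f/f reads and 26.5% of null reads (25.04 to 27.97) began at the commonest 5′ end, and 79.9% and 37.4% (35.8 to 39.0) ended at the commonest 3′ end.

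**Figure D3:**
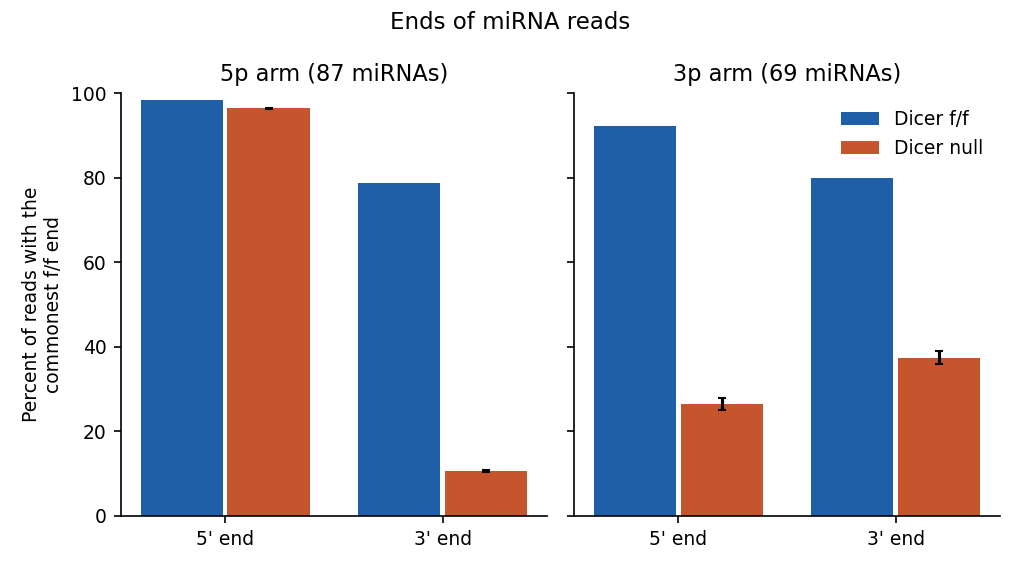
Percent of miRNA reads that share the commonest f/f 5′ or 3′ end, for the 5p and 3p arms in f/f and null; bars start at 0 and error bars on null are 95% binomial intervals. On the 5p arm the shared 5′ end stood at 98.4% and 96.5% while the shared 3′ end went from 78.7% to 10.6%.

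Of the 12 species more than 2-fold higher in null, 9 came from hairpins with a Mir symbol and 8 consisted mostly of reads of 24 nt or longer. The miR-183 cluster on chromosome 6 supplied miR-183-5p, 13.2-fold higher (12.2 to 14.4) with 94.4% of null reads at 24 nt or longer, and miR-182-5p, 2.86-fold higher with 93.5%. In f/f these shares were 3.37% and 83.1%, so long reads of miR-182-5p were not particular to null. From the Clcn5 intron on chromosome X (7248402 to 7248497), miR-532-5p was 5.42-fold higher (5.14 to 5.71) with 89.9% long reads, and from an intron of Cep170 miR-350-5p was 9.66-fold higher with 90.3%. When only reads of 18 to 23 nt were counted, 7 of the 12 were still more than 2-fold higher. miR-350-5p, miR-182-5p and miR-466c-5p were then nearly level, at log2 ratios of -0.07, 0.14 and 0.03, and miR-183-5p and miR-532-5p were lower, at -0.38 and -0.86. The value for miR-182-5p leaves out most of its f/f reads and rests on 128 f/f and 89 null reads. Other species above 2-fold were miR-582-5p (4.74-fold, intron of Pde4d), miR-6236-5p (5.06-fold) and miR-3535-5p (6.59-fold), the last in a hairpin that overlaps the snoRNA Gm24148 in Ncl. Predicted hairpins, whose reads were not tested for an origin in other RNA, gave the other 3 species. These were Gm44456-5p (3.14-fold), Gm44456-3p (8.90-fold) and a species shared by Gm22369 and its copies (31.2-fold). The last is uncertain because its reads fit several hairpins, as is Gm47295/Gm47299-3p, inside 7SL genes (1.08-fold higher). Below 100 f/f reads, miR-10b-5p, from the Hoxd cluster, had 10 f/f and 231 null reads, 36.5-fold higher (19.5 to 77.2), with 92.6% of null reads at 24 nt or longer. The species within 2-fold included miR-503-5p (1.20-fold higher), miR-335-5p (1.96-fold higher), miR-224-5p (1.59-fold lower), miR-96-5p (1.42-fold lower) and miR-15b-3p (1.25-fold lower). Counting only reads of 18 to 23 nt, 13 of the 18 species within 2-fold were more than 2-fold lower in null, 4 stayed within 2-fold and 1 was more than 2-fold higher. Of the 13, miR-503-5p was 15.3-fold, miR-335-5p 6.86-fold, miR-224-5p 6.34-fold, miR-96-5p 2.95-fold and miR-15b-3p 14.7-fold lower. At these lengths the reads assigned to miR-331-5p, 506 in f/f and 514 in null, stayed at a log2 ratio of 0.68. That label mixed unlike sequences: its commonest f/f form, of 21 nt, had 143 f/f and 2 null reads. Forms of 19 and 18 nt with a different sequence had 142 and 61 f/f reads and 253 and 167 null reads. The ratio of miR-331-5p therefore does not show that its 21-nt form was kept. Also at 18 to 23 nt, Gm47295/Gm47299-3p was at 0.33, miR-221-5p at -0.16 and miR-21a-3p at -0.68, while Gm47287/Gm47304/Gm47305-3p was at 1.76. Annotated miRNAs that overlap tRNA, snoRNA or other structured RNA were nearly level as a group, at 1.08 of the f/f CPM, with 4 of 6 species lower and 1 higher; the group's log2 ratio of 0.11 became -2.01 per snoRNA and snRNA read.

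Markers of other cell types differed in direction. They were scarce in null and, apart from miR-206-3p, miR-155-5p and miR-128-3p, also in f/f. The muscle marker miR-206-3p had 2236 f/f reads and no null read, at least 472-fold lower. The haematopoietic group was 6.00-fold lower (5.07 to 7.15), set mostly by miR-155-5p, which had 1290 f/f and 9 null reads. Its lowly expressed members miR-223-3p, of myeloid cells, and miR-142-3p, found across blood cells, had more reads in null, 38 against 9 and 25 against 10. Per snoRNA and snRNA read, their ratios were 1.54 (0.730 to 3.61) and 0.909 (0.422 to 2.12), so neither difference held on that scale, where the group had a log2 ratio of -4.70. The endothelial marker miR-126a-3p was 14.8-fold lower (8.55 to 28.2) and its group 16.2-fold lower. The neural group was 22.8-fold lower, led by miR-128-3p at 118-fold. Epithelial markers had 37 f/f and 285 null reads as a group, 12.2-fold higher in null, with miR-203-3p at 4 and 128 reads and miR-141-3p at 1 and 55 reads. All 128 null reads of miR-203-3p were shorter than 24 nt, and the source of these reads was not tested. The group stayed higher per snoRNA and snRNA read, at a log2 ratio of 1.49. Pluripotency markers had 3 f/f and 9 null reads. The hepatocyte marker miR-122 had 18 and 22 reads, a log2 ratio of 0.95 that became -1.17 per snoRNA and snRNA read. The imprinted Dlk1-Dio3 cluster had 17 and 25 reads, a log2 ratio of 1.22 that became -0.90 on that scale.

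A second comparison concerned the other RNA classes, which together were 5.24% of f/f and 17.0% of null, 3.25-fold higher (3.24 to 3.27). Small noncoding RNAs such as Y RNA and 7SL, which are not Dicer products, were 0.5003% of f/f and 4.398% of null, and Y RNA fragments supplied most of them. Rny1 (chromosome 6, 47788069 to 47788180, minus strand) went from 3665 to 30894 CPM, 8.43-fold higher (8.33 to 8.52), and Rny3 (chromosome 6, 47781624 to 47781725, plus strand) from 609 to 11299 CPM, 18.6-fold higher (18.1 to 19.1). The signal recognition particle RNA Rn7s1 was 1.49-fold higher, but its reads are shared with near-identical copies. Per snoRNA and snRNA read, the class of Y RNA and 7SL still had a log2 ratio of 1.02.

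Mitochondrial RNA was 0.220% of f/f and 1.49% of null, 6.77-fold higher. The 16S rRNA mt-Rnr2 was 5.85-fold higher, the 12S rRNA mt-Rnr1 15.0-fold higher and the histidine tRNA mt-Th 2.34-fold higher. Per snoRNA and snRNA read, the mitochondrial log2 ratio of 2.76 became 0.64. Fragments of snoRNA were 1.05% of f/f and 4.81% of null, led by Gm24452 (5.85-fold), Snord43 (4.92-fold) and Gm25789 (6.07-fold), with the U3 snoRNA Rnu3b1 at 3.43-fold in reads shared with copies. Spliceosomal snRNA was 0.107% of f/f and 0.229% of null: the U2 gene Rnu2-10 was 1.81-fold higher, the U1 gene Rnu1a1 1.78-fold higher and the U2-like Gm23444 11.5-fold higher, while the U5 gene Rnu5g was 1.36-fold lower. All but Rnu5g shared every read with copies. For Rnu5g, 97.8% of f/f and 37.3% of null reads matched no other gene, and on those it was 3.57-fold lower (3.22 to 3.97). The smaller miRNA share of null leaves a larger share there for any RNA at an unchanged level. A higher share alone therefore does not show a rise in the cells. As a class snRNA was 2.15-fold higher, and it, Rnu2-10, Rnu1a1 and mt-Th lay below the 3.25-fold of the other classes together. The 2 nuclear tRNA genes of the annotation used here had 47 f/f and 212 null reads, of which n-TSaga9 gave 33 and 174 and n-TStga1 14 and 38; their log2 ratio of 2.83 became 0.71 per snoRNA and snRNA read.

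Cytoplasmic rRNA as annotated was 2.31% of f/f and 1.05% of null. Nearly all of it was the 5S gene Rn5s, 2.19-fold lower in reads shared between copies, with smaller numbers for n-R5s109 (582 and 193 reads) and n-R5s88 (466 and 175 reads). Counting only reads of a single class changed the log2 ratio of rRNA from -1.13 to -0.17, and scaling to snoRNA and snRNA reads changed it to -3.25. Exons of mRNA and lncRNA were 1.05% of f/f and 5.06% of null, or 0.639% and 4.79% without Tmem38b and Dnm3os, and the genes with most reads in null beside Tmem38b were Gm42418 (6.93-fold higher), which overlaps an rRNA repeat, and B230208H11Rik (6.57-fold higher). Tmem38b was 1.13-fold higher and Dnm3os 56.2-fold lower, and both are uncertain. Without their last 3 nt, over 99.9% of the Tmem38b reads in either library also matched annotated rRNA, and 99.8% of the Dnm3os reads in f/f and 21.7% in null matched a miR-199 hairpin.

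**Figure D4:**
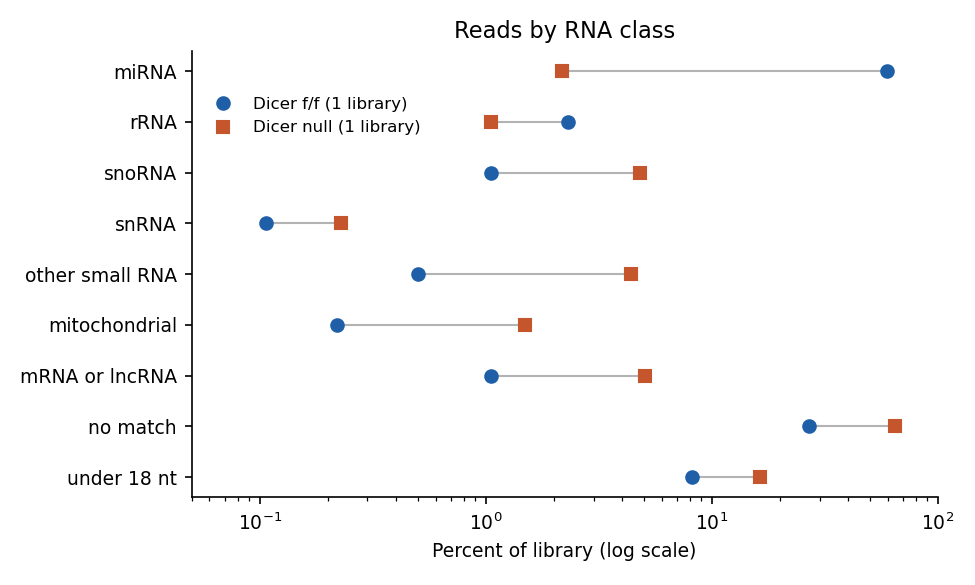
Percent of each library, on a log axis, in each RNA class for f/f and null. miRNA went from 59.6% to 2.17%, while snoRNA, Y RNA and 7SL, mitochondrial RNA and mRNA or lncRNA exons each took a larger share in null.

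The most abundant single sequences also changed. The leading 5 in f/f were the main forms of miR-22-3p, let-7c-5p, let-7b-5p, miR-16-5p and miR-145a-5p, with 703120, 680547, 361351, 285587 and 237653 reads. In null these forms had 197, 265, 261, 276 and 66 reads. The leading null sequence, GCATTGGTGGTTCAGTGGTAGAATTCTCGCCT, had 119136 null and 4101 f/f reads and matched no transcript used here, as did its forms shorter by 1 and 2 nt with 71748 and 55412 null reads. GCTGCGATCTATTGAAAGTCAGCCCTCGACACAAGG, also without a match, had 74535 null and 32975 f/f reads. The fifth was the Rny1 fragment GGCTGGTCCGAAGGTAGTGAGTTATCTCAA, with 50910 null and 11565 f/f reads.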

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

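Of the tests in this part, that of a fixed share carried over from f/f was set before its result was seen and the others were chosen after; the snoRNA and snRNA scale was planned for the miRNA share, let-7 and the median, but not as a test of miR-451a. Reads outside the main measurement were plentiful: reads without a match to any transcript used here were 27.02% of f/f and 64.5% of null, and reads under 18 nt were 8.15% of f/f and 16.3% of null. Both exceed what a count of 0 allows, and reads under 18 nt were not assigned to any RNA.

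The null library kept 136378 miRNA reads. A fixed share of f/f reads or cells would leave every miRNA at 1 common ratio (2.30%), but 70.1% of the miRNAs tested (110 of 157) lay more than 2-fold from it beyond their counting interval, 82 below and 28 above, and miR-22-3p limits any such share to 0.0562% of null reads. Random breakage is argued against by the 96.5% of 5p reads that kept the commonest f/f 5′ end. Hairpins cut by Drosha, left uncut by Dicer and then broken remain open as a biological candidate explanation tied to the genotype: on the 3p arm only 26.5% of null reads kept the Dicer-made 5′ end, as this explanation needs, but the Drosha-made 3′ end was also kept by only 37.4% of reads against 79.9% in f/f, below the level of at least 0.5 of f/f set for it. The medians per miRNA, over 35 miRNAs with at least 20 null reads, were 39.2% and 69.1%, which meets that level, so the answer on the 3p arm depends on how the reads are pooled. The 5p arm was not part of this test. There 96.5% of null reads kept the Drosha-made 5′ end and 10.6% the Dicer-made 3′ end, against 98.4% and 78.7% in f/f, a pattern this explanation also needs.

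miR-451a was higher in null while nearly all other abundant miRNAs were lower. Loss of the other miRNAs from a fixed total was tested per snoRNA and snRNA read. The ratio was 1.18 (0.982 to 1.42), an interval that includes 1 as this explanation needs. That scale cannot decide it, because snoRNA reads were themselves 4.57-fold more frequent in null (4.54 to 4.60). Per read of the library miR-451a was 5.11-fold higher (4.27 to 6.16), above the 3.25-fold of the other classes together. Blood or serum RNA in the null culture was tested on the other blood miRNAs with fewer than 1000 f/f reads, whose summed ratio at 18 to 23 nt was 1.28 (0.983 to 1.67) over 9 species. That sum decided nothing, because its members went apart: miR-223-3p was 6.67-fold higher (3.17 to 15.7) and miR-142-3p 3.95-fold higher (1.83 to 9.22), while miR-150-5p had 16 f/f and 2 null reads. Serum, other cells, index crosstalk, Dicer-independent processing and loss from a fixed total stay open for miR-451a. The first 3 were not tested for miR-203-3p and miR-141-3p, also higher in null.

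For the reads without a match, both explanations tested have evidence on their side, each in 1 library. In null, 13.9% ended in CCA, the end of mature tRNA, against 3.26% of reads from mRNA or lncRNA, which is in line with tRNA fragments. In f/f, 38.3% began with 18 nt of an annotated miRNA hairpin, against 1.52% in null, which is in line with miRNAs carrying untemplated 3′ bases or mismatches. The other unmatched null reads were not placed: tRNA fragments that stop before the 3′ end carry no CCA, so they stay open.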

How the results depend on the processing

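The alternatives with reads of 18 to 23 nt only, with Mir symbols only and with biotypes as annotated, the snoRNA and snRNA scale for RNA classes and single miRNAs, and mRNA or lncRNA without Tmem38b and Dnm3os, were chosen after the results were seen; the others were planned. miRNA, let-7 and the median stayed lower in null in every alternative run, and their sizes depended on the scale. From a log2 ratio of -4.78, the miRNA share moved to -3.03 per matched read, -4.29 with reads of 18 to 30 nt, -6.90 per snoRNA and snRNA read, -4.56 with sequences seen at least 10 times, -4.45 with a match of the first 18 nt, -4.36 with reads of a single hairpin, -4.79 without hairpins that overlap structured RNA, -6.67 with miRNA reads of 18 to 23 nt over all reads, -4.91 with Mir symbols only and -4.52 with biotypes as annotated. In the order of the first 6 of these settings, let-7 moved from -6.34 to -4.59, -5.84, -8.46, -6.05, -6.27 and -5.18, and with reads of 18 to 23 nt to -8.25; the 3 settings that leave let-7 hairpins untouched changed nothing by construction. The median of -5.18 moved to -3.42 per matched read, -4.61 with 18 to 30 nt, -7.30 per snoRNA and snRNA read, -6.24 with 18 to 23 nt, and to -3.40 and -6.49 with minima of 10 and 1000 f/f reads. Species without null reads were set to the floor of 3 counts, which limits how low the ratio of a scarce miRNA can go. The value with a minimum of 10 therefore does not show that scarce miRNAs were less reduced. The share of 21 to 23 nt moved from 71.1% in f/f to 79.3% in a window of 20 to 24 nt, 74.1% with sequences seen at least 10 times and 85.5% of matched reads, and from 18.3% in null to 27.2%, 18.6% and 15.7%. The log2 ratio of the other classes together moved from 1.70 to 2.52 with reads of a single class and 1.84 with sequences seen at least 10 times. Of the remaining results, miR-183-5p and miR-532-5p reversed with reads of 18 to 23 nt, to -0.38 and -0.86, because most of their null reads are longer. Counted as pairs of a remaining result and a setting, 23 others moved and 5 stayed the same, so 1 result can be in both counts. Beyond what each setting removes by construction, the cause was not tested. A match anywhere in the hairpin was not run, since it equals the rule used. No paired analysis was possible because each genotype had 1 library. Depth limited miRNAs with few null reads, of which 36 had none.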

Other observations

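The test in this part and the features it describes were chosen after the results were seen. In the f/f library, many miRNA reads carried 1 to 3 untemplated bases, and the base differed by miRNA. Over 67 miRNAs, A tails reached 30.3% of reads for miR-15a-5p, 28.1% for let-7i-5p, 22.6% for miR-26b-5p and 22.2% for miR-20a-5p. U tails reached 60.8% for miR-23b-3p, 54.7% for miR-143-3p, 46.1% for miR-24-3p and 27.9% for miR-152-3p. The 8 let-7 species of a single member had a median of 7.66% A tails and 0.125% U tails, against 4.77% and 2.21% over the 59 others. Reads shared by let-7a and let-7c (0% A and 0.371% U tails) were left out. An added base equal to the next hairpin base counted as templated. Several let-7 hairpins continue with U after the main form, so their low U shares were partly set by the method. The hairpins of let-7e-5p and let-7i-5p continue with G, and these had 2.56% and 2.73% U tails.

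Sequences that begin GCATTGGTGGTTCAG, without a match in the transcripts used here, were 0.522% of f/f and 5.86% of null, 11.2-fold higher (11.1 to 11.3). Those that begin GCATGGGTGGTTCAG were 0.0696% and 1.11%, 15.9-fold higher, and those that begin TCCCTGGTGGTCTAG 0.0358% and 0.523%, 14.6-fold higher.

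Reads of 16 nt were 3.897% of f/f and 6.199% of null. In f/f, the last 16 nt of the main form exceeded 5% of its reads for 20 of 49 miRNAs (median 8.29%, 7.34% to 11.6%), while the last 15 and the last 17 nt did so for 0 of 49. For miR-22-3p this form, CCAGTTGAAGAACTGT, had 68199 reads, 9.70% of the main form. The trimming tool is not given in the sources used here, and whether the 16-nt forms existed in the cells or arose in trimming was not tested.

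The main form of a miRNA was taken as its commonest matched f/f read of at least 18 nt. For miR-23a-3p this read, of 19 nt with 43607 f/f reads, itself lacked the first bases of a 22-nt form with 15860. The test used here could not count such a case. For 2 of 157 miRNAs tested, f/f reads without the first bases outnumbered the main form. TGAAATCGGTT of miR-29a-3p had 27071 reads against 1878, and CGAACTTGTG of miR-100-5p 16240 against 1426. Removal of sequence that resembles the end of the 5 prime cloning adapter (CGATC) is a candidate explanation. Of these 2 cut points, 100% followed bases within 1 mismatch of that end, against 1.81% of 1549 others. However, they are the ones that raised the idea and are too few. The bases missing from the 19-nt form of miR-23a-3p are also the last bases of that end, but this case was outside the test. The question therefore stays open. Levels of miR-29a-3p and miR-100-5p counted here leave those short reads out.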
